A study of Mus musculus with 31 samples.

How the data were processed

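Total RNA of mouse colon was, per the labels, extracted with TRIzol, checked by NanoDrop and Bioanalyzer, and made into libraries with the VAHTS Universal V6 kit. Per the submitters' processing notes, the authors used fastp, HISAT2 and HTSeq with the genome build mm10. Their versions, the annotation, the gene lengths, the strand setting and the read layout are not given in the sources used here. The deposited table holds 1 column per library and 27623 genes, with values in FPKM (fragment counts scaled to gene length and library size) computed by the authors. The values are not whole numbers and their column sums differ between libraries. Within a gene and a library they should be whole multiples of the value of 1 fragment. For 473 genes, a median of 95.6% of values (85.3 to 97.7 over libraries) lay within 0.02 fragments of a whole number. These genes were picked for whole values in the libraries used to calibrate, and each total was chosen to make many values whole. The share is therefore no test of the relation. The same relation gave the total fragments behind each library, calibrated with 13 libraries, from 30800000 to 40400000 with a mean of 37000000. In WT replicate 4 only 2 values worth 1 fragment agreed on the total, and in DHO replicates 7 and 8 only 3 each. The file gives no counts, so counting intervals were not computed, and depth limits the precision of genes near 0 FPKM most. Near-identical paralogs share reads and their separate values are uncertain.

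Libraries were grouped by the genotype in the labels into WT (n = 11), HO (n = 10) and DHO (n = 10), all at day 7, and named by group and order of listing. The labels do not say that each library is a separate animal, and replicate numbers do not pair libraries between groups, so p-values measure the spread between these libraries. No pair of libraries had identical values, and the highest correlation between 2 libraries was 0.993. Gene positions were taken from a RefSeq annotation of GRCm38, the assembly also called mm10, in which 26637 of the 27623 symbols were found.

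The test fixed before the data were examined was a count model, and it could not be used because the file holds FPKM. In its place, limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 0.5) with 1 mean per group over all 31 libraries, a variance trend and robust empirical Bayes moderation. Genes with at least 1 FPKM in at least 10 libraries were tested (12812 genes). The p-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05 and no limit on fold change. The comparisons were HO with WT, DHO with HO and DHO with WT.

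Of 38 gene lists fixed before the data were examined, the 33 with at least 5 tested members were tested with fry (limma), whose directional p asks whether the members of a list move on balance one way and does not compare them with other genes. These p-values were adjusted over the 33 lists. Beside it, camera was run with a preset correlation and with a correlation estimated for each list. Camera compares the members of a list with the other genes, so it asks another question than fry. A high estimated correlation weakens this test. For the epithelium list in HO against WT, the adjusted p was 2.13e-05 with the preset correlation and 0.491 with the estimated one (0.935). The lists cover epithelial lineages and programmes, other cell types and tissues, position along the gut, and RNA handling. A list score is the mean log2 value of its tested members. Members absent from the file were Trac, Igha, Igkc, Tpsab1, Try5, Amy2b, Sprr1b, Mx1, Mx2, Cxcl11 and Pla2g2a, which were not analysed here.

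Genes are named by a rule fixed before the data were examined. It takes Map3k7, Tradd and Ripk1, the 8 largest increases and 8 largest decreases past the threshold in each comparison among expressed genes whose group medians lie on the side of the change, and those with the smallest p of each list (up to 4 for a called list and 2 for any other). The rule leaves out of the naming genes without an established symbol, antigen receptor segments, pseudogenes, Xist and Y-linked genes. Some genes that the rule takes are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

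No batch is named in the labels. A division of the libraries was read from the noncoding RNA Gm15564 after the data were seen, and each comparison was repeated in batch 1 alone, in batch 2 alone and with batch as a term, and the difference of the effects between batches was tested as an interaction in limma, also without the DHO libraries of batch 2 in turn and without DHO replicates 8 and 9 together. The reversal between the comparisons was measured over 40 random splits of the HO and WT libraries. Depth was compared between groups with two-sided permutation tests of 100000 resamples in SciPy 1.17.1. For each comparison 100 splits of the libraries into groups of the same sizes were counted, the real split included. Alternatives tried were the scaling of the libraries, the filter on low values, the added constant, robust and weighted fits, a minimum fold change, fits of the compared groups alone, covariates for Xist and for smooth muscle, the omission of each library in turn, and the omission of libraries that stood apart.

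The pipeline was tested on simulated data with the same groups, in which 200 of 12812 genes were changed by 0.5, 1, 2 or 4 on the log2 scale. For HO and WT it recovered 50%, 86%, 96% and 100% of the genes of these sizes with 6 false calls (3.49% of calls). For DHO and HO it recovered 48%, 76%, 94% and 100% with 8 false calls (4.79%), and for DHO and WT 46%, 92%, 94% and 100% with 13 false calls (7.26%). The shifted list was recovered, and 0 of the unshifted lists were called. The simulated genes varied independently, with the same spread in all groups, and few were changed. In the data, list members were correlated (0.935 estimated for the epithelium list), and 9148 genes were called between HO and WT. The false calls in the simulation are therefore no measure of those in the data. Figures were drawn with Matplotlib 3.10.9.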

Results

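RNA sequencing measured gene expression in colon tissue of mice at 7 days post induction, in 31 libraries that fall into 3 genotype groups. The WT group (n = 11) kept intact floxed Tak1 alleles on a Ripk1 D138N/D138N background, a mutation that inactivates the kinase of RIPK1. The HO group (n = 10) lacked TAK1 in intestinal epithelial cells (IEC), and the DHO group (n = 10) lacked both TAK1 and TRADD in these cells, on the same Ripk1 background. TAK1, encoded by Map3k7, is a kinase downstream of TNF and Toll-like receptors that activates NF-kB and MAP kinase signalling. TRADD is an adaptor protein of the TNF receptor complex, and RIPK1 is a kinase and scaffold in that complex. The Cre driver and the inducing agent are not given in the sources used here. The stated question is what TRADD contributes to the colitis of mice without epithelial TAK1.

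The deposited FPKM values (fragment counts scaled to gene length and library size) implied between 30800000 and 40400000 fragments per library. Mean depth was 37600000 ± 2360000 fragments (SD, n = 11) in WT, 35900000 ± 3990000 (n = 10) in HO and 37500000 ± 2710000 (n = 10) in DHO. No pair of groups differed in depth past the threshold in a two-sided permutation test (p = 0.246 for HO against WT, 0.291 for DHO against HO and 0.965 for DHO against WT; adjusted over the 3 tests, 0.436, 0.436 and 0.965). The first principal component held 77.9% of the variance and placed the HO libraries between 44.9 and 150 and the WT libraries between -77.9 and -64.4. The DHO libraries lay between -76.3 and 51.3 on the same axis. HO replicate 2 (44.9), DHO replicate 8 (51.3) and DHO replicate 9 (25.5) stood apart from the rest of their groups.

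The libraries also divided in a way that crossed the genotype groups. The noncoding RNA Gm15564 (chromosome 16, 35966751 to 35983329) lay between 0 and 0.0736 FPKM in 17 libraries and between 6.27 and 14.5 FPKM in the other 14. The labels name no batch, and these sets are called batch 1 (6 WT, 5 HO and 6 DHO libraries) and batch 2 (5 WT, 5 HO and 4 DHO libraries). Of the 12812 genes tested, 1027 separated the 2 sets in the same direction within all 3 groups.

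**Figure D1:**
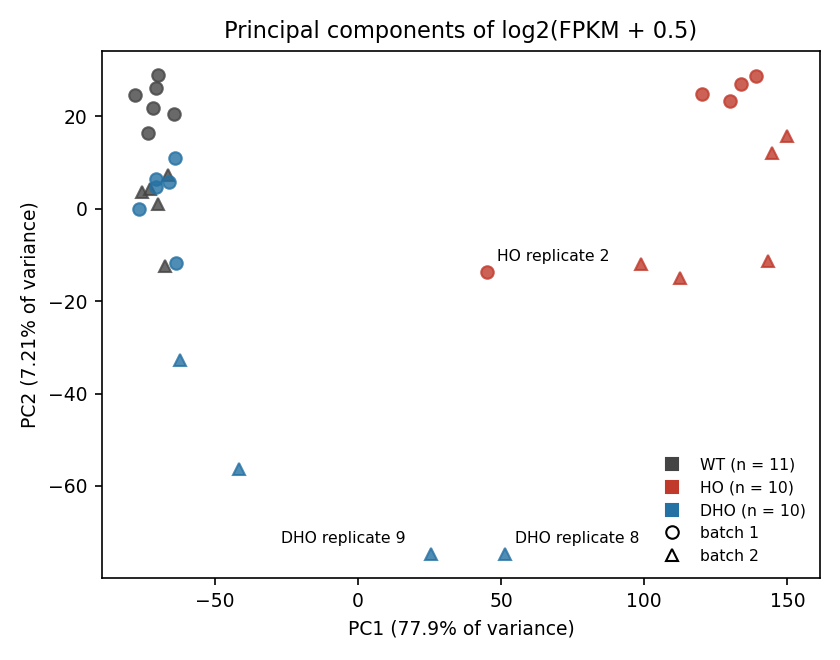
Position of each library on the first and second principal components of log2(FPKM + 0.5), with the share of variance on each axis (77.9% and 7.21%), colour for the group and shape for the batch. The HO libraries lie between 44.9 and 150 on the first component, with HO replicate 2 nearest to the other groups, and DHO replicates 8 (51.3) and 9 (25.5) lie apart from the other DHO libraries.

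The targeted genes were examined first in every group. Tradd (chromosome 8, 105258575 to 105264594, GRCm38) was at 73.2 ± 22 FPKM (SD, n = 11) in WT, 22.9 ± 13.7 (n = 10) in HO and 2.80 ± 0.943 (n = 10) in DHO. Tradd fell by 2.72 on the log2 scale (SE 0.228, limma adjusted p = 1.31e-11) between HO and DHO, and all 10 DHO libraries (1.36 to 3.89 FPKM) lay below all 10 HO libraries (12.4 to 59.2 FPKM). The change between HO and DHO was -3.18 in batch 1 alone (adjusted p = 8.56e-10) and -2.27 in batch 2 alone (adjusted p = 7.57e-06). Tradd was also lower in HO than in WT, by a log2 fold change of -1.75 (SE 0.223, adjusted p = 3.04e-08), with -1.67 in batch 1 alone (adjusted p = 2.69e-06) and -1.76 in batch 2 alone (adjusted p = 9.40e-06). HO replicate 2, with a WT-like score on the epithelium list (8.31, WT 8.28 to 8.69), had 59.2 FPKM of Tradd. The other HO libraries had 18.8 ± 5.36 FPKM. The lower Tradd in HO was thus not separated from the loss of epithelial transcripts. Map3k7 (chromosome 4, 31963492 to 32023470) was at 10.5 ± 1.39 FPKM in WT, 13.5 ± 1.48 in HO and 11.4 ± 2.85 in DHO. It was higher in HO than in WT (log2 fold change 0.35, SE 0.103, adjusted p = 0.00362), with 0.39 in batch 1 alone (adjusted p = 0.00432) and 0.29 in batch 2 alone (adjusted p = 0.0272). With the smooth muscle score as a covariate that change was -0.0292 (adjusted p = 0.852). That score did not overlap between HO (5.25 to 6.63) and WT (6.97 to 8.34), so the covariate can take out the genotype difference itself. Map3k7 was lower in DHO than in HO (-0.27, SE 0.106, adjusted p = 0.0264), with -0.46 in batch 1 alone (adjusted p = 0.00107) and 0.0421 in batch 2 alone (adjusted p = 0.762). Gene-level values over whole tissue count fragments from undeleted exons and from other cell types, so that Map3k7 expression does not measure the deletion. Ripk1 (chromosome 13, 34002225 to 34035170) was higher in HO than in WT by a log2 fold change of 0.39 (SE 0.0782, adjusted p = 6.04e-05), and its point mutation cannot be read from expression.

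**Figure D2:**
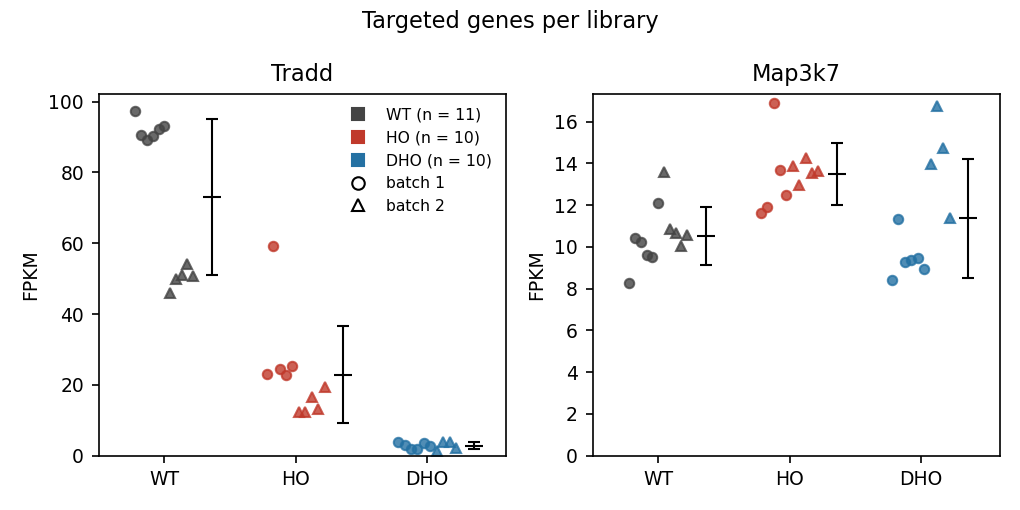
FPKM of Tradd and Map3k7 in each library, with the mean and SD of each group (WT n = 11, HO n = 10, DHO n = 10) and the batch as the shape of the point. All 10 DHO libraries lie between 1.36 and 3.89 FPKM for Tradd, below the lowest HO library (12.4), whereas Map3k7 lies between 8.29 and 16.9 FPKM over the 3 groups.

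The comparison of HO with WT asks what loss of epithelial TAK1 does to the colon when the kinase of RIPK1 is inactive. The epithelium, colonocyte and goblet cell lists were lower in HO, with median falls of more than an order of magnitude. The enteroendocrine and stem cell lists fell less (median log2 fold changes of -1.79 and -2.03), and the tuft cell list was not called. Transcripts of neutrophils, macrophages, inflammatory cytokines and matrix enzymes were higher. The chloride and bicarbonate exchanger Slc26a3 went from 395 ± 139 FPKM (SD, n = 11) in WT to 1.49 ± 4.46 (n = 10) in HO, a mean that rests on HO replicate 2 (14.2 FPKM; 0.0758 ± 0.114 without it). The calprotectin subunit S100a8 went from 1.48 ± 1.48 FPKM in WT to 11050 ± 6640 in HO, with all 10 HO libraries (2643 to 20950 FPKM) above all 11 WT libraries (0.397 to 5.51 FPKM). Changes are log2 fold changes with their SE, over 10 HO and 11 WT libraries, and those of genes near 0 FPKM in either group depend on the 0.5 FPKM added before the logarithm. Each list has an adjusted p from fry and one from camera with a correlation estimated for that list. List members are counted as higher or lower over all genes tested. Over all libraries, counts adjusted over the list alone equal these where no other count is given.

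All 14 members of the epithelium list fell, with a median of -5.35 (fry adjusted p = 1.04e-08; adjusted p = 0.491 with an estimated correlation). They include the adhesion protein gene Cdh1 (-5.10 ± 0.506, adjusted p = 2.07e-10) and the transcription factor gene Hnf4a (-6.16 ± 0.581, adjusted p = 7.23e-11). Of 19 colonocyte genes tested, 18 fell and 1 did not pass (median -5.86, fry adjusted p = 3.99e-12; adjusted p = 0.491 with an estimated correlation). Among them were Slc26a3 (-8.89 ± 0.529), the water channel gene Aqp8 (-9.49 ± 0.593) and the carbonic anhydrase gene Car4 (-5.11 ± 0.378). Of 13 goblet cell genes, 12 fell and 1 did not pass (median -5.66, fry adjusted p = 4.79e-10; adjusted p = 0.491 with an estimated correlation). Members that changed include the mucus proteins Zg16 (-10.26 ± 0.892) and Clca1 (-9.34 ± 0.613) and the trefoil peptide Tff3 (-9.25 ± 0.759). Of 10 enteroendocrine genes, 8 fell and 2 rose (median -1.79, fry adjusted p = 4.32e-07; adjusted p = 0.497 with an estimated correlation), with the peptide hormones Insl5 (-5.44 ± 0.402) and Pyy (-4.35 ± 0.525) among those that fell. HO replicate 2 did not show the loss on the epithelium list. Its score (mean log2 value of the list) was 8.31, within the WT range (8.28 to 8.69), and the other 9 HO libraries lay between 0.298 and 5.70. Without it, the medians were -5.92 for epithelium, -6.18 for colonocytes and -6.33 for goblet cells (no library HO 2).

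The stem cell and crypt base list had 12 of 15 members lower, 1 higher and 2 not past the threshold (median -2.03, fry adjusted p = 1.10e-13; adjusted p = 0.491 with an estimated correlation). The Wnt target Axin2 fell by 2.34 on the log2 scale (SE 0.145), and the stem cell receptor Lgr5 fell by 2.28 (SE 0.167). Of 21 proliferation genes, 16 fell and 5 did not pass (median -0.78, fry adjusted p = 0.0111; adjusted p = 0.706 with an estimated correlation). Among them were Mki67 (-1.56 ± 0.254) and the topoisomerase Top2a (-1.29 ± 0.306). In batch 2 alone 4 of these 21 genes fell and the list was not called (median -0.757, fry adjusted p = 0.183), against 15 in batch 1 alone (median -0.762, adjusted p = 0.0379), and the batches did not differ past the threshold (interaction test, fry adjusted p = 0.986). Xenobiotic and steroid metabolism fell in 17 of 18 members and rose in 1 (median -4.79, fry adjusted p = 2.92e-10; adjusted p = 0.491 with an estimated correlation). The sulfotransferase Sult1b1 changed by -6.67 ± 0.406 and the cytochrome Cyp3a13 by -4.93 ± 0.385. Of 17 genes of fatty acid oxidation and ketogenesis, 12 fell and 4 rose (13 and 4 adjusted over the list alone; median -1.03, fry adjusted p = 1.38e-07; adjusted p = 0.497 with an estimated correlation). Acadm, a dehydrogenase of medium-chain fatty acids, fell by 1.68 (SE 0.146), and the lipase inhibitor gene Angptl4 rose by 4.80 (SE 0.331).

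Neutrophil genes rose in 19 of 20 members and fell in 1 (median 7.84, fry adjusted p = 1.10e-13; adjusted p = 0.491 with an estimated correlation). S100a8 rose by 12.40 ± 0.955 and the granule protein gene Ngp by 11.17 ± 0.610. Monocyte and macrophage genes rose in 17 of 18 members and fell in 1 (median 3.13, fry adjusted p = 1.78e-13; adjusted p = 0.491 with an estimated correlation). The endotoxin co-receptor Cd14 changed by 3.57 ± 0.237 and Adgre1, the gene of the F4/80 antigen, by 3.72 ± 0.261. All 16 inflammatory cytokine and chemokine genes tested rose (median 7.34, fry adjusted p = 5.81e-11; adjusted p = 0.491 with an estimated correlation). Csf3, the granulocyte growth factor, rose by 8.29 ± 0.580, the neutrophil chemokine Cxcl3 by 7.84 ± 0.610 and the monocyte chemokine Ccl2 by 7.40 ± 0.614. NF-kB targets rose in 13 of 16 members and fell in 1 (median 1.63, fry adjusted p = 1.23e-09; adjusted p = 0.491 with an estimated correlation). Members that changed include the inhibitor gene Nfkbie (3.23 ± 0.306) and the adhesion molecule Icam1 (4.46 ± 0.400). Matrix remodelling genes rose in 16 of 17 members and fell in 1 (median 4.71, fry adjusted p = 1.74e-11; adjusted p = 0.491 with an estimated correlation). The protease inhibitor Timp1 changed by 6.76 ± 0.493 and the membrane protease Mmp14 by 2.96 ± 0.200.

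Antimicrobial and epithelial defence genes went in both directions, with 7 of 15 higher and 4 lower (7 and 5 adjusted over the list alone; median 1.58, fry adjusted p = 9.86e-08; adjusted p = 0.513 with an estimated correlation). The acute phase protein Saa3 had the largest increase of the named genes (13.97 ± 0.909), and the siderophore-binding Lcn2 rose by 10.24 ± 0.568. Interferon gamma and antigen presentation genes rose in 19 of 22 members and 3 did not pass (median 1.45, fry adjusted p = 2.38e-05; adjusted p = 0.497 with an estimated correlation). Members that changed include the chemokine Cxcl9 (6.03 ± 0.794) and the peptide transporter Tap1 (2.48 ± 0.275). Of 18 type I interferon response genes, 11 rose and 2 fell (median 1.15, fry adjusted p = 0.0171; adjusted p = 0.684 with an estimated correlation). The double-stranded RNA sensors Oas1a (-1.38 ± 0.151) and Oas2 (1.996 ± 0.302) moved in opposite directions. In batch 2 alone the type I list was not called (median 1.16, fry adjusted p = 0.0914), whereas in batch 1 alone it was (median 1.09, adjusted p = 0.00585), with no difference between the batches past the threshold (interaction test, fry adjusted p = 0.854).

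The cell death machinery list had 11 of 23 members higher and 10 lower. Its median was 0.02 and its mean -0.589, and the directional test called it lower (fry adjusted p = 0.000143; adjusted p = 0.940 with an estimated correlation, in the opposite direction). The members with the largest decreases were Gsdmc4 (-9.04 ± 0.329) and Gsdmc2 (-6.97 ± 0.287) of the gasdermin C family. The cell death list was not tested without them, so its call was not separated from the loss of epithelial transcripts. In batch 2 alone that list was not called (mean -0.59, fry adjusted p = 0.162), and in batch 1 alone it was (mean -0.586, adjusted p = 0.000228), with a change of the same size (interaction test, fry adjusted p = 0.986). In the TAK1 complex and TNF receptor signalling list, 13 of 21 members rose and 3 fell (median 0.385, fry adjusted p = 8.79e-08; adjusted p = 0.491 with an estimated correlation). Among them were the ubiquitin ligase Birc3 (1.29 ± 0.151) and the A20-binding protein Tnip1 (1.17 ± 0.131). Unfolded protein response genes rose in 8 of 14 members and fell in 1 (median 0.544, fry adjusted p = 1.54e-05; adjusted p = 0.497 with an estimated correlation). Epithelial regeneration genes rose in 11 of 17 members and fell in 5 (median 1.34, fry adjusted p = 0.000270; adjusted p = 0.600 with an estimated correlation). HO replicate 7, with the lowest epithelium score (0.298), scored 5.415 on this list, above all WT libraries (at most 4.88). The rise therefore does not show a programme of epithelial cells, and which cells carried it was not tested.

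Markers of the other cell types of the colon wall moved apart in these libraries. Smooth muscle genes fell in all 12 members (median -1.68, fry adjusted p = 2.74e-06; adjusted p = 0.497 with an estimated correlation). Smooth muscle myosin Myh11 changed by -1.94 ± 0.285. Fibroblast genes rose in 9 of 12 members (median 1.14, fry adjusted p = 5.55e-06; adjusted p = 0.497 with an estimated correlation). The proteoglycan gene Dcn rose by 2.63 ± 0.324. Endothelial genes rose in 9 of 11 members, and in 10 adjusted over the list alone (median 1.97, fry adjusted p = 3.05e-09; adjusted p = 0.491 with an estimated correlation). The vascular cadherin gene Cdh5 rose by 2.58 ± 0.240. Of the 7 genes of distal colon position, 6 fell and 1 rose (median -2.30, fry adjusted p = 1.06e-08; adjusted p = 0.491 with an estimated correlation). The homeobox genes Hoxb13 and Hoxa13 fell by 7.64 (SE 0.533) and by 2.30 (SE 0.244), and Hoxa11 rose by 1.91 (SE 0.139).

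The limma test across 12812 genes called 9148 between HO and WT at an adjusted p of 0.05, of which 4232 were higher and 4916 lower in HO, and 4295 of the calls differed by at least 2-fold. It called 8774 genes in batch 1 alone and 8671 in batch 2 alone. The effect differed between the batches for 0 genes (interaction test in limma; 377 at an unadjusted p under 0.05). Of 33 lists tested with fry, 29 were called, 17 higher and 12 lower. Camera with an estimated correlation called 0 lists, with 1 at an unadjusted p under 0.05. The median over all genes was -0.06, so the list medians are close to changes relative to all genes.

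**Figure D3:**
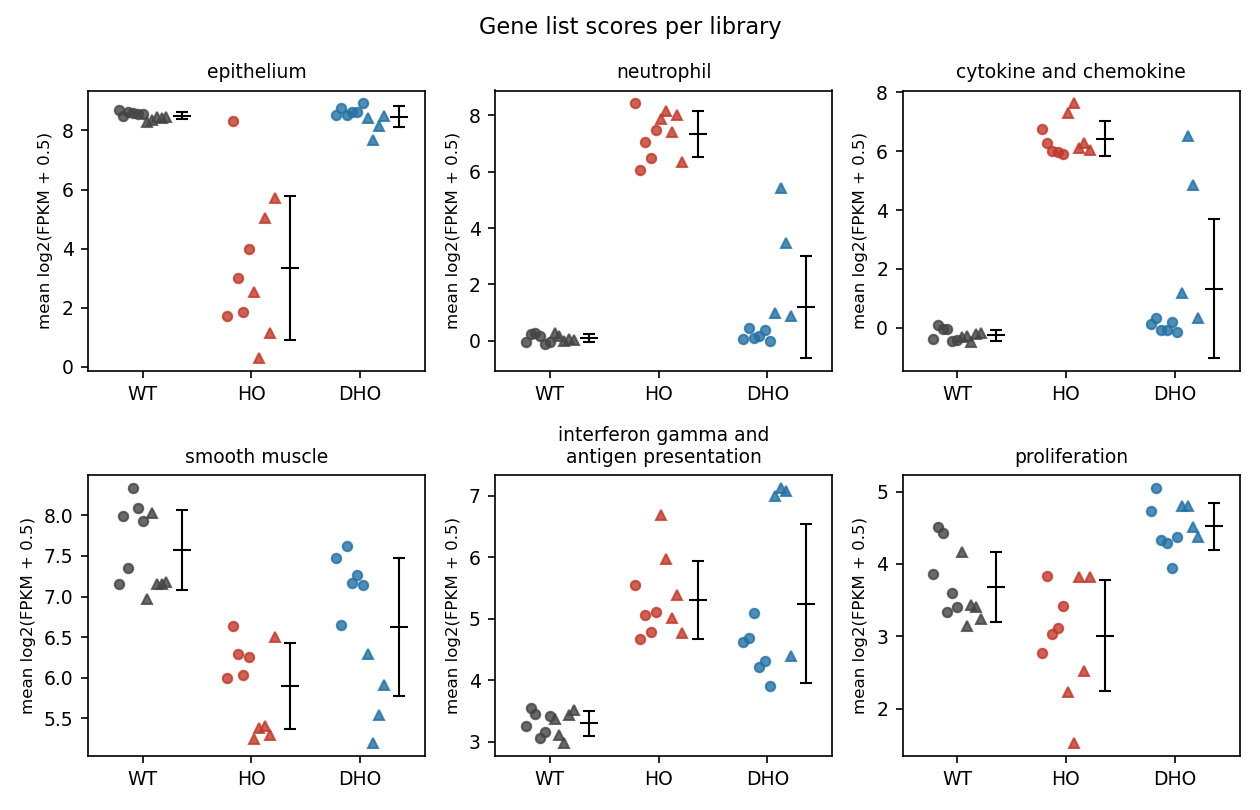
Mean log2(FPKM + 0.5) of the members of 6 gene lists in each library, with the mean and SD of each group (WT n = 11, HO n = 10, DHO n = 10) and the batch as the shape of the point. Between HO and WT the epithelium list has a median change of -5.35 and the neutrophil list of 7.84, and between DHO and WT the interferon gamma list has a median change of 1.76.

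The comparison of DHO with HO asks what TRADD contributes in the TAK1-deficient epithelium. Epithelial transcripts were higher in DHO than in HO, and neutrophil, macrophage, cytokine and matrix transcripts were lower. Slc26a3 was at 174 ± 114 FPKM (SD, n = 10) in DHO against 1.49 ± 4.46 (n = 10) in HO (0.0758 without HO replicate 2). S100a8 was at 213 ± 560 FPKM in DHO (38.6 ± 104 without DHO replicate 8, which had 1780) against 11050 ± 6640 in HO. DHO replicates 8 and 9 had neutrophil scores of 5.43 and 3.46, and the highest of the other 8 DHO libraries had 0.977. Changes are over 10 DHO and 10 HO libraries.

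All 14 epithelium genes rose (median 5.32, fry adjusted p = 1.99e-08; adjusted p = 0.479 with an estimated correlation). Cdh1 changed by 5.17 ± 0.518 and Hnf4a by 5.80 ± 0.595. All 19 colonocyte genes rose (median 5.93, fry adjusted p = 1.03e-10; adjusted p = 0.412 with an estimated correlation). Aqp8 changed by 8.44 ± 0.607 and Slc26a3 by 7.28 ± 0.542. All 13 goblet cell genes rose (median 6.08, fry adjusted p = 6.92e-10; adjusted p = 0.412 with an estimated correlation). Zg16 changed by 9.96 ± 0.913. Of 10 enteroendocrine genes, 8 rose and 2 fell (median 2.18, fry adjusted p = 2.19e-08; adjusted p = 0.516 with an estimated correlation). Stem cell and crypt base genes rose in 13 of 15 members and fell in 1 (median 1.93, fry adjusted p = 3.40e-12; adjusted p = 0.412 with an estimated correlation), and Lgr5 rose by 1.87 ± 0.171. All 21 proliferation genes rose (median 1.64, fry adjusted p = 1.89e-06; adjusted p = 0.541 with an estimated correlation). Mki67 changed by 2.21 ± 0.260 and Top2a by 2.23 ± 0.313. Xenobiotic and steroid metabolism genes rose in 15 of 18 members and fell in 1 (median 3.42, fry adjusted p = 1.79e-07; adjusted p = 0.541 with an estimated correlation). Genes of fatty acid oxidation and ketogenesis rose in 12 of 17 members and fell in 4 (median 0.825, fry adjusted p = 0.000431; adjusted p = 0.749 with an estimated correlation), and in batch 2 alone that list was not called (median 0.572, fry adjusted p = 0.0958; interaction test, fry adjusted p = 0.27).

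Neutrophil genes fell in 19 of 20 members and rose in 1 (median -6.58, fry adjusted p = 6.46e-12; adjusted p = 0.412 with an estimated correlation). S100a8 changed by -10.16 ± 0.978 and Ngp by -10.24 ± 0.625. The neutrophil median was -7.47 in batch 1 alone and -5.08 in batch 2 alone, and the 2 batches did not differ in this list past the threshold (interaction test, fry adjusted p = 0.103). Monocyte and macrophage genes fell in 17 of 18 members and rose in 1 (median -2.01, fry adjusted p = 1.38e-10; adjusted p = 0.412 with an estimated correlation). Adgre1 changed by -2.89 ± 0.267. All 16 cytokine and chemokine genes fell (median -5.48, fry adjusted p = 1.99e-08; adjusted p = 0.412 with an estimated correlation). Csf3 changed by -7.24 ± 0.593 and Cxcl3 by -6.58 ± 0.624. NF-kB targets fell in 14 of 16 members (14 lower and 1 higher adjusted over the list alone; median -1.20, fry adjusted p = 6.39e-08; adjusted p = 0.412 with an estimated correlation). Nfkbia changed by -2.99 ± 0.225. Matrix remodelling genes fell in 16 of 17 members (median -3.36, fry adjusted p = 6.92e-10; adjusted p = 0.412 with an estimated correlation). Timp1 changed by -5.38 ± 0.504. TAK1 complex and TNF receptor signalling genes fell in 13 of 21 members and rose in 4 (median -0.313, fry adjusted p = 4.26e-08; adjusted p = 0.412 with an estimated correlation), and in batch 2 alone the list was not called (median -0.208, fry adjusted p = 0.0672; interaction test, fry adjusted p = 0.071). Tradd, deleted in DHO, is a member of this list (-2.72), so part of the fall was set by the genotype.

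Cell death machinery genes rose in 13 of 23 members and fell in 8 (median 0.573, fry adjusted p = 1.03e-10; adjusted p = 0.638 with an estimated correlation). Gsdmc4 changed by 8.64 ± 0.336. In HO, Gsdmc4 was at most 1.89 FPKM, and Gsdmc2 and Gsdmc3 of the same list were at most 0.464 and 0.0244 FPKM. The list mean was 0.951, above its median. The list was not tested without these genes, so its call was not separated from the rise of epithelial transcripts. Antimicrobial and epithelial defence genes rose in 7 of 15 members and fell in 6. The median of that list was 0.667 and its mean -0.71, and the directional test called it lower (fry adjusted p = 0.0199; adjusted p = 0.834 with an estimated correlation). It was not called in batch 2 alone, where the mean was 0.316 against -1.46 in batch 1 alone (adjusted p = 0.995 and 4.48e-07). The batches did not differ in this list past the threshold (interaction test, fry adjusted p = 0.0669). Nor was it called without HO replicate 2 (no library HO 2, mean -0.289, adjusted p = 0.0629, in the opposite direction). Saa3 fell by 11.16 (SE 0.930) and Lcn2 by 8.49 (SE 0.581). The interferon lists were not called. Of 22 interferon gamma and antigen presentation genes, 8 were higher and 3 lower (5 and 3 adjusted over the list alone; median 0.247, mean -0.0605, fry adjusted p = 0.576). Of 18 type I genes, 5 were higher and 2 lower (4 and 2 adjusted over the list alone; median 0.326, fry adjusted p = 0.1; 0.0474 with batch as a term, and 0.859 by camera with an estimated correlation and that term), with Oas1a at 1.80 ± 0.155. Smooth muscle genes rose in 8 of 12 members, and in 9 adjusted over the list alone (median 0.74, fry adjusted p = 0.0265; adjusted p = 0.820 with an estimated correlation), which was 0.202 in batch 2 alone (adjusted p = 0.709; interaction test, fry adjusted p = 0.109). Fibroblast genes fell in 10 of 12 members (median -1.39, fry adjusted p = 2.11e-07; adjusted p = 0.412 with an estimated correlation), and endothelial genes fell in all 11 members (median -1.96, fry adjusted p = 6.92e-10; adjusted p = 0.412 with an estimated correlation).

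The limma test called 8805 genes between DHO and HO, 4996 higher and 3809 lower in DHO, and 4017 differed by at least 2-fold. The excess of higher genes depended on the processing. Median-of-ratios scaling gave 4573 higher and 4257 lower, and no low-value filter gave 5971 higher and 6097 lower. It called 8958 genes in batch 1 alone and 7681 in batch 2 alone, and for 568 genes the effect differed between the batches (interaction test in limma at an adjusted p of 0.05). That count was 9 without DHO replicate 8 and 8 without DHO replicate 9, but 1365 without DHO replicate 7 and 3084 without DHO replicate 10. It was 0 without replicates 8 and 9, with 1180 at an unadjusted p under 0.05. Of 33 lists, 0 differed between the batches by fry with all libraries, 9 without DHO replicate 7 and 14 without DHO replicate 10. The median over all genes was 0.10, and it was 0.03 with median-of-ratios scaling. Of 33 lists tested with fry, 26 were called, 13 in each direction, and camera with an estimated correlation called 0, with 0 at an unadjusted p under 0.05.

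Both of these comparisons contain the HO libraries, so opposite changes arise in part from the shared values. Genes were therefore called between 5 HO and 5 WT libraries, and DHO was compared with the other 5 HO libraries, in 40 random splits. Over the splits, a median of 7580 genes was called. The genes higher in HO had a median change of -1.03 (range over splits -1.27 to -0.804) in DHO against the unused HO libraries, and the genes lower in HO had a median of 1.02 (0.666 to 1.19). The sign was opposite in a median of 96.2% of the higher genes and 97.0% of the lower genes. Without a split, the medians were -0.852 and 0.828. The covariance of the 2 sets of changes was -2.43 with the split and -2.46 without it, and in 100 simulations with no effect it had a median of -0.0183 without a split. Over all libraries, 3418 genes were higher in HO than in WT and lower in DHO than in HO, 4191 were lower and then higher, and 22 and 4 moved in the same direction in both comparisons.

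The comparison of DHO with WT asks what remains different when TAK1 and TRADD are both deleted. By fry, the lists of interferon response, antigen presentation and cell death machinery were higher in DHO than in WT, over all libraries and in each batch alone. Those of proliferation (higher) and of smooth muscle and xenobiotic metabolism (lower) were called over all libraries but not in batch 1 alone. Camera with an estimated correlation called 0 lists (3 at an unadjusted p under 0.05), and 0 of 14 epithelium genes passed the threshold (limma, 0 at an unadjusted p under 0.05). The spread in that limma test includes the HO libraries, which varied widely in epithelial genes. The immunoproteasome subunit Psmb9 was at 68.5 ± 29.05 FPKM (SD, n = 10) in DHO and 20.6 ± 6.01 (n = 11) in WT. The chloride channel regulator family member Clca4b had the largest increase of the named genes, from 2.79 ± 1.74 FPKM in WT (1.24 to 6.99) to 264 ± 269 FPKM in DHO (20.1 to 806). The effect differed between the batches for 1256 genes (interaction test in limma at an adjusted p of 0.05). That count depended on which of the 4 DHO libraries of batch 2 were used. It was 1 without replicate 8, 3 without replicate 9, 2068 without replicate 7 and 3797 without replicate 10. It was 0 without replicates 8 and 9, with 762 at an unadjusted p under 0.05. Of 33 lists, 15 differed between the batches by fry, 14 without replicate 7, 5 without replicate 8, 0 without replicate 9, 18 without replicate 10, and 0 without replicates 8 and 9. Changes are over 10 DHO and 11 WT libraries.

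All 22 interferon gamma and antigen presentation genes rose (median 1.76, fry adjusted p = 4.37e-05; adjusted p = 0.319 with an estimated correlation). The list was called in batch 1 alone (median 1.08, 11 genes higher, fry adjusted p = 0.000708) and in batch 2 alone (median 2.71, 22 genes higher, adjusted p = 0.00193), and the interaction test gave a fry adjusted p of 0.0132, which was 0.0555 without DHO replicate 9 and 0.402 without replicates 8 and 9. The scores in batch 2 were 6.99, 7.13 and 7.08 in DHO replicates 7, 8 and 9 and 4.39 in replicate 10, against 3.91 to 5.09 in the DHO libraries of batch 1. Without replicates 8 and 9 the list was still called (no libraries DHO 8 and DHO 9, median 1.38, 20 genes higher, adjusted p = 0.000249). Psmb9 rose by 1.65 ± 0.194 (adjusted p = 3.17e-06; 1.24 in batch 1 alone and 2.18 in batch 2 alone), and the peptide-loading gene H2-DMb1 rose by 1.93 ± 0.254 (adjusted p = 1.49e-05; 1.35 and 2.80). The tryptophan-degrading enzyme Ido1 rose by 3.73 ± 0.636 (adjusted p = 0.000381), with 2.07 in batch 1 alone (adjusted p = 0.0793) and 6.17 in batch 2 alone (adjusted p = 0.000789). Type I interferon response genes rose in 14 of 18 members, and in 17 adjusted over the list alone (median 1.21, fry adjusted p = 0.000828; adjusted p = 0.375 with an estimated correlation). Their median was 0.692 in batch 1 alone (adjusted p = 0.00813) and 2.05 in batch 2 alone (adjusted p = 0.00713). The nucleic acid sensor Zbp1 rose by 2.13 ± 0.329 (1.62 and 2.91 by batch).

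Cell death machinery genes rose in 9 of 23 members and fell in 1 (12 and 1 adjusted over the list alone; median 0.284, fry adjusted p = 2.78e-05; adjusted p = 0.319 with an estimated correlation). Their median was 0.168 in batch 1 alone (adjusted p = 0.00813) and 0.514 in batch 2 alone (adjusted p = 0.000939). Ripk3, the kinase of necroptosis, rose by 1.54 ± 0.213 (adjusted p = 3.10e-05; 1.02 in batch 1 alone, adjusted p = 0.0565, and 2.27 in batch 2 alone, adjusted p = 0.000298). Its effector gene Mlkl rose by 1.27 ± 0.212 (adjusted p = 0.000295; 0.88 in batch 1 alone, adjusted p = 0.00152, and 1.90 in batch 2 alone, adjusted p = 0.000894), and the TNF receptor gene Tnfrsf1b rose by 1.42 ± 0.265. Proliferation genes rose in 18 of 21 members, and in 20 adjusted over the list alone (median 0.891, fry adjusted p = 0.00610; adjusted p = 0.375 with an estimated correlation). In batch 1 alone that list was not called (median 0.624, adjusted p = 0.122), and in batch 2 alone it was (median 1.15, adjusted p = 0.0423), although the batches did not differ past the threshold (interaction test, fry adjusted p = 0.383). Aurora kinase Aurka rose by 1.20 ± 0.283 and the ribonucleotide reductase subunit Rrm2 by 1.48 ± 0.364. The rise of the proliferation list was not separated from a division within WT, given below with the clock genes. Antimicrobial and epithelial defence genes rose in 8 of 15 members, and in 9 adjusted over the list alone (median 1.75, fry adjusted p = 0.000525; adjusted p = 0.329 with an estimated correlation). The protease inhibitor Slpi rose by 3.22 ± 0.387. Their median was 0.602 in batch 1 alone (adjusted p = 0.0528) and 2.82 in batch 2 alone (adjusted p = 0.000306). Epithelial regeneration genes rose in 4 of 17 members (6 higher and 1 lower adjusted over the list alone; median 0.667, fry adjusted p = 0.0177; adjusted p = 0.497 with an estimated correlation), and in batch 1 alone that list was not called (median 0.131, adjusted p = 0.628). The surface antigen Ly6a rose by 2.001 ± 0.210 (adjusted p = 3.37e-07; 1.60 and 2.58 by batch).

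T and NK cell genes rose in 6 of 10 members, and in 8 adjusted over the list alone (median 0.782, fry adjusted p = 0.00131; adjusted p = 0.375 with an estimated correlation). Among them were the granzymes Gzma (2.61 ± 0.338) and Gzmb (1.80 ± 0.287). Monocyte and macrophage genes rose in 11 of 18 members and fell in 1 (13 and 1 adjusted over the list alone; median 0.752, fry adjusted p = 0.00633; adjusted p = 0.375 with an estimated correlation). The monocyte antigen gene Ly6c2 rose by 1.59 ± 0.340. In batch 1 alone neither the T and NK cell list (median 0.328, adjusted p = 0.0528) nor the macrophage list (median 0.313, adjusted p = 0.0528) was called, and in batch 2 alone both were (medians 1.54 and 1.41, adjusted p = 0.00713 and 0.0162). Cytokine and chemokine genes rose in 4 of 16 members, and in 5 adjusted over the list alone (median 1.34, fry adjusted p = 0.0371; adjusted p = 0.505 with an estimated correlation). Their median was 0.202 in batch 1 alone (adjusted p = 0.347) and 3.52 in batch 2 alone (adjusted p = 0.0162), where the scores were 6.52 and 4.85 in DHO replicates 8 and 9 and 1.19 and 0.339 in replicates 7 and 10. Without replicates 8 and 9 that list was not called (no libraries DHO 8 and DHO 9, median 0.299, adjusted p = 0.0905). The neutrophil list was not called, with 3 of 20 members higher (median 1.11, fry adjusted p = 0.0760; 0.0431 with batch as a term, and 0.638 by camera with an estimated correlation and that term), nor were NF-kB targets, with 4 of 16 higher and 1 lower (median 0.325, adjusted p = 0.184). Unfolded protein response genes rose in 8 of 14 members (median 0.396, fry adjusted p = 0.00602; adjusted p = 0.375 with an estimated correlation). The chaperone Hspa5 changed by 0.83 ± 0.182 and the transcription factor Xbp1 by 0.39 ± 0.0855, and in batch 1 alone that list was not called (median 0.259, adjusted p = 0.250).

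Of the 14 epithelium genes, 0 passed the limma test in DHO against WT, and 0 passed adjusted over the list alone or at an unadjusted p under 0.05 (median 0.02, mean -0.02, fry adjusted p = 0.971). The gene with the smallest p was Hnf4a (-0.36 ± 0.581, adjusted p = 0.696). The spread in these tests was estimated over all 3 groups, and the HO scores on this list ran from 0.298 to 8.31. The SE of Hnf4a was the same in HO against WT. Smaller changes could thus be missed, and these tests do not show that DHO and WT are equal. Goblet cell genes (1 of 13 higher, median -0.273, fry adjusted p = 0.849), colonocyte genes (1 of 19 higher and 5 lower, median -1.05, adjusted p = 0.344) and stem cell genes (1 of 15 higher and 2 lower, 2 and 4 adjusted over the list alone, median -0.19, adjusted p = 0.344) were not called as lists. DHO replicates 8 and 9 lay below all WT libraries in 3 of these scores. Their goblet scores were 3.95 and 4.64 (WT 5.78 to 6.74, other DHO 5.90 to 7.47). Their colonocyte scores were 4.32 and 5.13 (WT 6.71 to 7.21, other DHO 6.41 to 7.60). Their epithelium scores were 7.66 and 8.16 (WT 8.28 to 8.69). Slc26a3 fell by 1.61 (SE 0.529, adjusted p = 0.0298), with -0.51 in batch 1 alone (adjusted p = 0.754) and -3.19 in batch 2 alone (adjusted p = 0.00307). Xenobiotic and steroid metabolism genes fell in 7 of 18 members, and in 9 adjusted over the list alone (median -0.943, fry adjusted p = 0.0375; adjusted p = 0.451 with an estimated correlation). The largest decrease was that of the cytochrome Cyp2c55 (-4.01 ± 0.850, adjusted p = 0.00230; -1.81 in batch 1 alone, adjusted p = 0.313, and -7.26 in batch 2 alone, adjusted p = 0.000187). In batch 1 alone the xenobiotic list had a median of -0.324 (adjusted p = 0.642) and in batch 2 alone of -1.84 (adjusted p = 0.00294). It was not called without DHO replicates 8 and 9 (no libraries DHO 8 and DHO 9, median -0.533, adjusted p = 0.185), nor were fatty acid oxidation and ketogenesis genes (median -0.131, adjusted p = 0.124). Fatty acid oxidation and ketogenesis genes fell in 5 of 17 members (1 higher and 7 lower adjusted over the list alone; median -0.30, fry adjusted p = 0.0177; adjusted p = 0.375 with an estimated correlation). In batch 1 alone that list was not called (median -0.0921, adjusted p = 0.628), and in batch 2 alone 11 of its genes fell (median -0.641, adjusted p = 0.00713). Smooth muscle genes fell in 11 of 12 members, and in 12 adjusted over the list alone (median -0.944, fry adjusted p = 0.00610; adjusted p = 0.375 with an estimated correlation). Myh11 changed by -1.03 ± 0.285 and the myosin kinase Mylk by -0.73 ± 0.158. Their median was -0.597 in batch 1 alone (adjusted p = 0.0528) and -1.61 in batch 2 alone (adjusted p = 0.00294). Of the 7 genes of distal colon position, 3 fell (median -0.777, fry adjusted p = 0.00810; adjusted p = 0.375 with an estimated correlation). Hoxd12 changed by -1.24 ± 0.364, and in batch 1 alone that list was not called (median -0.763, adjusted p = 0.191).

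Dbp, Tef and Nr1d1, output genes of the circadian clock, were lower in DHO than in WT, and no list tested covers the clock. The transcription factor Dbp fell by 3.51 (SE 0.684, adjusted p = 0.00130; -2.51 in batch 1 alone, adjusted p = 0.229, and -4.87 in batch 2 alone, adjusted p = 0.00276). Its relative Tef fell by 2.08 (SE 0.438) and the clock repressor Nr1d1 by 2.11 (SE 0.367). In WT, Dbp was under 3 FPKM in 4 libraries and over 50 FPKM in 7, and the 10 DHO libraries lay between 0.355 and 2.87 FPKM. The proliferation score divided WT in the same way, with 3.86 to 4.51 in those 4 libraries and 3.14 to 3.60 in those 7 (DHO 3.94 to 5.05). So did the unfolded protein response score (4.97 to 5.24 and 4.61 to 4.90, DHO 4.97 to 5.56). The rise of these 2 lists in DHO against WT was thus not separated from this division of WT. The labels give no time of collection. The chemokine Ccl20, a target of NF-kB, fell by 2.31 (SE 0.359, adjusted p = 0.000142), with -2.80 in batch 1 alone (adjusted p = 0.00311) and -1.72 in batch 2 alone (adjusted p = 0.0346).

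**Figure D4:**
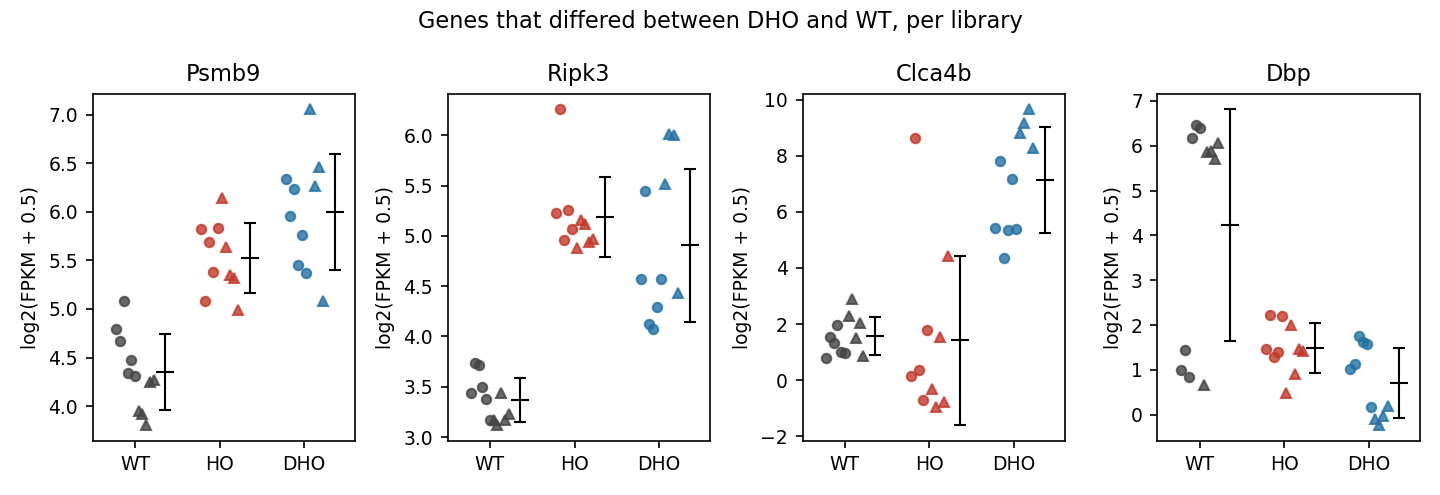
log2(FPKM + 0.5) of Psmb9, Ripk3, Clca4b and Dbp in each library, with the mean and SD of each group (WT n = 11, HO n = 10, DHO n = 10) and the batch as the shape of the point. Between DHO and WT, Psmb9 rose by 1.65, Ripk3 by 1.54 and Clca4b by 5.58 on the log2 scale, and Dbp fell by 3.51, with the WT libraries of Dbp in 2 separate sets.

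The limma test called 2719 genes between DHO and WT, 1604 higher and 1115 lower in DHO, and 462 differed by at least 2-fold (243 without DHO replicate 8, 248 without DHO replicate 9 and 137 without both). With median-of-ratios scaling it called 2852 genes, 1363 higher and 1489 lower, so that 47.8% rather than 59.0% were higher. It called 68 genes in batch 1 alone (48 higher and 20 lower) and 5102 in batch 2 alone (2701 higher and 2401 lower), and 4550 with batch as a term. Without DHO replicates 8 and 9 it called 1302 genes, 787 higher and 515 lower (no libraries DHO 8 and DHO 9). Of 116 genes that the naming rule takes for this comparison, 41 kept their direction and side of the threshold in batch 1 alone. Of 33 lists tested with fry, 16 were called, 12 higher and 4 lower (10 without DHO replicate 8 and 11 without DHO replicate 9), and camera with an estimated correlation called 0, with 3 at an unadjusted p under 0.05. In batch 1 alone 3 lists were called, those of interferon gamma and antigen presentation, type I interferon response and cell death machinery.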

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

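The tests of splits of the libraries were planned, and the tests of epithelial share, scaling, gut position, label exchange, batch and clock were chosen only after the results were seen.

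For each comparison, 100 splits of its libraries into groups of the same sizes were compared, and 1 of the 100, the real split, gave the real number of genes. Between HO and WT the real split gave 9148 genes and the highest of the others 6017, between DHO and HO 8805 and 1999, and between DHO and WT 2719 and 1607. In each comparison the median of the other splits was 0 genes. No other split reached the real count, which argues against chance as the source of these counts. A test of 100 splits cannot give a share below 1 in 100. The splits took no account of batch and treated each library as a separate animal.

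The first pattern is the loss of epithelial transcripts in HO. A lower share of epithelium alone raises the markers of every other cell type alike. The fibroblast score rose by 1.14 (SE 0.183) and the smooth muscle score fell by 1.67 (SE 0.224), a gap of 2.81 (SE 0.265) on the log2 scale, which argues against that share as the whole explanation. The scaling of the FPKM values is argued against by the median change of the epithelium list, which was -5.33 after median-of-ratios scaling. What stays open is a loss of epithelial cells together with a change in the cells of the wall, a loss of expression within cells, a different stretch of colon in the HO samples, and the deletion of TAK1 itself, none of which was tested apart.

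The second pattern is HO replicate 2, where a value lay far from the other 9 HO libraries for 27 of the 39 values found in this way, out of 264 tested (each gap to the nearest library was above Dixon's critical value for 10 libraries, which chance gives in about 1 in 20 groups; WT, with 11 libraries, was not tested). A milder change in the same stretch of distal colon is argued against by the log2 ratio of Hoxb13 to Vil1, which was -8.49 there and between -1.47 and 1.45 in the WT and DHO libraries, and an exchange of labels with a WT or DHO sample of the series by its neutrophil score of 6.05 (at most 0.285 in WT) and its Tradd of 59.2 FPKM (at most 3.89 in DHO). A candidate explanation is a sample from another stretch of gut. Hoxb6, chosen with Hoxc10 after their values were seen, was above all 30 other libraries (17.5 FPKM against at most 3.05), as was Hoxc10 (2.07 against 0.0761), and Hoxd13 was at 0 FPKM against at least 4.90. The sampled stretch is not in the labels, so a sample from outside the series and a difference in the animal stay open too.

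The values of HO replicate 2 that lay far from its group were list scores (mean log2 value) and FPKM. It was highest in the scores of skeletal muscle (2.18), small intestine (2.69), colonocyte (5.67), goblet cell (5.87), antimicrobial and epithelial defence (7.55), and xenobiotic and steroid metabolism (3.77). It was highest in the FPKM of Tradd (59.2), Slc26a3 (14.2), Aqp8 (14.2), Clca1 (24.5), Zg16 (1130), Tff3 (394), Gsdmc2 (0.464), Gsdmc4 (1.89), Sult1b1 (11.5) and Cyp3a13 (6.64). It was also highest in Sycn (25.6), Spink1 (54.4), Retnlb (283), Ripk3 (76.2), Ly6a (1530), Cyp2c55 (20.5) and Pck1 (14.4), and lowest in Hoxd13 (0) and Hoxa13 (0.351).

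The third pattern is the set of 2719 genes called between DHO and WT. WT (6 and 5 libraries in batches 1 and 2) and DHO (6 and 4) were nearly balanced over the batches. A library batch that shifts every group alike could therefore add little to their difference. All 2719 genes were called in the same direction with batch as a term (4550 genes called). The balance nearly fixed that result in advance, so it is no separate evidence. A linear trend in Arntl and Npas2 as the whole cause is argued against by a fit of the 21 WT and DHO libraries with that trend, in which Dbp (-2.20, SE 0.549, limma adjusted p = 0.0135), Nr1d1 (-1.88, SE 0.408, adjusted p = 0.00709), Tef (-1.31, SE 0.389, adjusted p = 0.0259), Psmb9 (1.61, SE 0.231, adjusted p = 0.000438), Ripk3 (1.63, SE 0.250, adjusted p = 0.000771) and Clca4b (5.80, SE 0.622, adjusted p = 2.14e-05) stayed past the threshold, and 2041 genes were called both without (2669) and with (2493) the trend. DHO was also compared by limma with the 4 WT libraries whose Arntl (3.74 to 4.25 FPKM) was at or above the lowest of DHO (1.77 to 4.19 FPKM). There 15 genes were called (1295 at an unadjusted p under 0.05), among them Clca4b (5.66, SE 0.893, adjusted p = 0.0246). Dbp (-0.27, SE 0.386, adjusted p = 0.757) and Tef (-0.0993, SE 0.317, adjusted p = 0.896) were near 0. Nr1d1 was at -1.10 (SE 0.486, adjusted p = 0.476). Psmb9 (1.37, SE 0.313, adjusted p = 0.173, unadjusted p = 0.000576) and Ripk3 (1.39, SE 0.368, adjusted p = 0.225, unadjusted p = 0.00192) were not called. Their changes were close to those against all WT libraries (1.65 and 1.54). What stays open for Dbp, Tef and Nr1d1 is the phase of the clock by another relation than that trend. Open for the set are the time of collection (not in the labels), genotype, and the state of DHO replicates 8 and 9. Without replicates 8 and 9, 1302 genes were called, and 0 of the 1256 effects that differed between the batches did so (limma, 762 at an unadjusted p under 0.05).

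Other values that lay far from the rest of their group were as follows. In HO replicate 10 the score of immediate early and heat shock genes was highest at 5.90, Mptx1 at 5.19 FPKM and Cma1 at 1.93 FPKM. In HO replicate 6, H2-DMb1 was highest at 46.9 FPKM and Fabp4 lowest at 107 FPKM. In DHO replicate 8, Ngp (80.3 FPKM), Cd14 (188 FPKM) and Tnip1 (52.4 FPKM) were highest and Sult1b1 was lowest (18.7 FPKM). Mki67 was lowest in DHO replicate 5 (17.1 FPKM), and Hoxd13 was lowest in DHO replicate 6 (4.90 FPKM). In DHO replicate 4, Hoxc10 was highest at 0.0534 FPKM, close to 0.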

How the results depend on the processing

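The batch, pseudocount, quality weight, FPKM of at least 5, clock trend and left-out-set alternatives were chosen after seeing the data, and the others were planned. Of 6547 values of named genes under alternatives (393 gene and comparison pairs), 94.6% kept their side of the threshold and, where past it, their direction, 290 lost the call and 64 gained it. These leave out Map3k7 in HO against WT and Tradd in DHO against HO, and 20 of them changed sign, 19 of these past the threshold in neither setting. Without a minimum fold change, the called genes were 6323 to 13233 in HO against WT and 6080 to 12068 in DHO against HO. The lower ends come from the filter of FPKM of at least 5, which tests 8717 genes, and the upper ends from no low-value filter. Unless stated, the cause of a change was not tested. The planned count models and the planned filter on scaled counts were not run, since the file holds FPKM. Array quality weights (9679, 9639 and 3523 genes for HO against WT, DHO against HO and DHO against WT) and the filter of FPKM of at least 5 (6323, 6080 and 1946) took their place. The Xist covariate is void as a check of sex, since Xist was at most 0.0112 FPKM in every library.

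With a log2 fold change of at least 1 the calls were 4295, 4017 and 462 by construction. Camera with a preset correlation called 18 lists in HO against WT, 16 in DHO against HO and 19 in DHO against WT, and camera with an estimated correlation called 0, 0 and 0 in the 3 comparisons. With the smooth muscle score as a covariate, Map3k7 in HO against WT changed sign to -0.0292 (adjusted p = 0.852) and 6 lists were called in DHO against WT. Of the genes called there without this covariate, 970 of 2719 were called with it, and the 2-fold calls went from 462 to 177. In HO against WT, 6510 of 9148 were, 6452 of them in the same direction. The smooth muscle score itself differed between the groups, without overlap between HO and WT. Fits with this covariate can therefore remove genotype effects, and they do not check the calls. Map3k7 in DHO against HO was 0.0421 in batch 2 alone (adjusted p = 0.762); over the other alternatives for that value it lay between -0.48 (array quality weights) and -0.10 (smooth muscle score as a covariate). In DHO against WT, batch as a term gave 4550 genes, batch 1 alone 68 genes and 3 lists, batch 2 alone 5102 genes, no libraries DHO 8 and DHO 9 1302 genes, and no libraries HO 2, DHO 8 and DHO 9 1735 genes. Fewer libraries account for part of the smaller counts, but not for 68 beside 5102. The WT libraries with Dbp under 3 FPKM were replicates 1, 2 and 3 in batch 1 but only replicate 7 in batch 2. All DHO libraries were under 3 FPKM, so the batches were unlike in this respect. What this adds to the gap of 68 and 5102 was not tested. The reversal with the 200 smallest p was -4.09 for higher genes and 3.67 for lower genes. These genes were picked by p, and why their values were larger was not tested.

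Leaving out each library in turn gave 8893 to 9171 genes in HO against WT, 8540 to 8910 in DHO against HO, and 1840 (without DHO replicate 9) to 3040 in DHO against WT. The lists called were 28 to 29, 23 to 26 and 10 to 17, with 10 in DHO against WT without DHO replicate 8. Map3k7 in HO against WT was 0.31 to 0.38 and Tradd in DHO against HO -2.80 to -2.55. Pseudocounts of 0.1 and 1 changed the 2-fold calls to 4709 and 3883 in HO against WT, 4440 and 3519 in DHO against HO, and 657 and 337 in DHO against WT, where array quality weights gave 157. Fold changes of genes near 0 FPKM are what depth and this constant limit most.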

Other observations

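Genes of the enteric nervous system, of blood lineages and of other tissues also differed between the groups. Enteric neuron and glia genes were higher in HO than in WT in 11 of 13 members and lower in 1 (12 and 1 adjusted over the list alone; median 0.973, fry adjusted p = 1.01e-05; adjusted p = 0.497 with an estimated correlation). The neuropeptide Vip rose by 2.65 ± 0.253 (SE, n = 10 and 11). They were lower in DHO than in HO in 12 of 13 (median -1.16, fry adjusted p = 1.89e-06; adjusted p = 0.479 with an estimated correlation). They were not called between DHO and WT (1 of 13 lower, median -0.11, adjusted p = 0.497). B cell genes were not called in HO against WT (3 of 13 lower, median -0.37, fry adjusted p = 0.234). Nor were they in DHO against WT, where limma called 0 of 13, and 0 at an unadjusted p under 0.05 (median 0.506, fry adjusted p = 0.401). The list was called higher in DHO against HO, with 9 members not past the threshold (4 of 13 higher, and 3 adjusted over the list alone; median 0.883, adjusted p = 0.0465; adjusted p = 0.820 with an estimated correlation). Plasma cell genes were called higher as a list in DHO against WT (2 of 8 higher, and 3 adjusted over the list alone; median 0.656, fry adjusted p = 0.0259; adjusted p = 0.497 with an estimated correlation). They were not called in HO against WT (median -0.022, fry adjusted p = 0.468) or DHO against HO (3 of 8 higher and 2 lower, median 0.76, adjusted p = 0.0826; 0.0453 with batch as a term, and 0.829 by camera with an estimated correlation and that term). T and NK cell genes were called higher in HO against WT, with 5 of 10 members higher (median 0.626, fry adjusted p = 0.00155; adjusted p = 0.620 with an estimated correlation). They were not called in DHO against HO (median 0.286, adjusted p = 0.602). Immediate early and heat shock genes, which can respond to tissue handling, were called higher in HO against WT (6 of 14 higher, median 0.455, fry adjusted p = 2.14e-05; adjusted p = 0.497 with an estimated correlation). They were called lower in DHO against HO (5 lower and 2 higher, 5 and 1 adjusted over the list alone; median -0.207, adjusted p = 0.0199; adjusted p = 0.749 with an estimated correlation). They were called higher in DHO against WT, with 11 members not past the threshold (3 of 14 higher, median 0.50, adjusted p = 0.0371; adjusted p = 0.507 with an estimated correlation). Mitochondrially encoded genes differed between the batches in WT, with scores of 6.41 to 7.80 in batch 1 and 9.04 to 9.37 in batch 2. Without a batch term that list was not called in HO against WT (median -0.678, fry adjusted p = 0.101), DHO against HO (0.386, 0.357) or DHO against WT (-0.264, 0.513). With batch as a term it was called lower in HO against WT (median -0.814, 10 of 13 lower, fry adjusted p = 5.26e-05; adjusted p = 0.592 with an estimated correlation) and higher in DHO against HO (0.516, 7 higher, adjusted p = 0.00242; 0.738 with an estimated correlation), and not called in DHO against WT (-0.137, adjusted p = 0.268). In HO against WT the median was -0.823 in batch 1 alone (adjusted p = 0.00585) and -0.733 in batch 2 alone (adjusted p = 0.000926).

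Tuft cell genes were not called in HO against WT (median 0.267, fry adjusted p = 0.271) or DHO against WT (median -0.0927, adjusted p = 0.270). The list was called lower in DHO against HO, with 4 members not past the threshold (1 of 5 lower, median -0.171, adjusted p = 0.0359; adjusted p = 0.744 with an estimated correlation). Small intestine genes fell in HO against WT (4 of 7 lower and 2 higher, median -1.22, fry adjusted p = 8.96e-06; adjusted p = 0.669 with an estimated correlation). They rose in DHO against HO (4 higher and 1 lower, median 1.12, adjusted p = 6.39e-08; adjusted p = 0.552 with an estimated correlation) but were not called in DHO against WT (median 0.357, adjusted p = 0.0983). The distal colon position list rose in DHO against HO (5 of 7 higher and 1 lower, 6 and 1 adjusted over the list alone; median 1.38, fry adjusted p = 6.28e-05; adjusted p = 0.638 with an estimated correlation). Adipocyte genes were called higher in HO against WT with a median of 0.748 and a mean of -0.234 (2 of 5 higher and 1 lower, fry adjusted p = 0.00362; adjusted p = 0.700 with an estimated correlation). In DHO against HO they were called lower (median -0.302, adjusted p = 0.000403; adjusted p = 0.744 with an estimated correlation), and they were not called in DHO against WT (median -0.332, adjusted p = 0.351). In DHO against HO, epithelial regeneration genes (6 of 17 higher and 9 lower, median -0.657, fry adjusted p = 0.251) and unfolded protein response genes (median 0.0503, mean -0.223, adjusted p = 0.133) were not called. In DHO against WT, fibroblast genes (median -0.217, adjusted p = 0.274), endothelial genes (median -0.164, adjusted p = 0.401) and enteroendocrine genes (median 0.39, adjusted p = 0.261) were not called. Neither were matrix remodelling genes (5 of 17 higher and 1 lower, 9 and 1 adjusted over the list alone; median 0.665, fry adjusted p = 0.182) and TAK1 complex genes (median 0.08, mean -0.129, adjusted p = 0.722). The TAK1 complex list holds Tradd, which is deleted in DHO and was at -4.47. The lists of mast cell and eosinophil (3 tested, median -0.374 in HO against WT), pancreas (1 tested, -5.80), skeletal muscle (4 tested, -1.09), erythroid (4 tested, 2.16) and squamous epithelium (1 tested, -0.684) had fewer than 5 tested members and no list test. Xist lay at or below 0.0112 FPKM in every library, and the labels give no sex.

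B3gnt9, which neighbours Tradd on chromosome 8 (105252638 to 105255250), was singled out after its values were seen, and the test of it was chosen only then. A hypothesis was that transcription from the deleted Tradd allele runs into it, so that B3gnt9 but not Fbxl8, on the other side of Tradd, would be higher in DHO than in HO, and than in WT, in each batch. B3gnt9 was higher by 0.99 in batch 1 (SE 0.194, limma adjusted p = 0.000213) and by 0.66 in batch 2 (SE 0.234, adjusted p = 0.0271). Fbxl8 was higher too in batch 1 (0.43, SE 0.182, adjusted p = 0.0443) and not past the threshold in batch 2 (0.22, SE 0.197, adjusted p = 0.338). Against WT, B3gnt9 was higher in DHO by 2.09 in batch 1 (adjusted p = 9.99e-06) and by 1.42 in batch 2 (adjusted p = 0.00190), and Fbxl8 was not past the threshold (-0.209 and -0.436, adjusted p = 0.575 and 0.0920). In HO against WT, where Tradd is not deleted, B3gnt9 was higher too (0.919, SE 0.213, adjusted p = 0.000302) and Fbxl8 was lower (-0.68, SE 0.209, adjusted p = 0.00471), so both genes also moved without that deletion. The comparison with WT meets the hypothesis and the one with HO does not, and the higher B3gnt9 stays open.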
